A study of Mus musculus with 50 samples.

How the data were processed

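Polyadenylated RNA of splenic B cells was sequenced from stranded libraries. Per the labels, the cells came from pooled male and female C57BL/6 wild-type mice of 8 to 12 weeks, were purified by depleting CD43-positive cells, and were cultured with 10 µg/ml anti-IgM. Each of 25 times from 0 to 360 min, 15 min apart, has 2 libraries that the labels call biological replicates. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, Trimmomatic 0.36, STAR 2.7.0e and RSEM 1.3.1 on the GRCm38.p6 genome. The labels do not state whether the counting used the strand of the reads.

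The deposited tables give, per gene and library, RSEM expected counts, which are the authors' estimate of reads per gene without normalization. Of all these values 7.75% are not whole numbers, and of those above 0 23.33% are not. The same deposited tables give TPM, transcript abundance scaled within each library, which the authors computed with RSEM. Expected counts, rounded to whole numbers, were used throughout, and TPM in 2 alternatives. The matrices of all libraries repeat the tables per library and were not used here. Of 54838 gene IDs 54809 matched GENCODE M21 once the version was ignored, and the 29 others hold 0.0019% of the counts. Names and coordinates (GRCm38, counted from 1) are those of GENCODE M21.

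Depth was 14916063 to 20508138 expected counts per library. Ratios of genes with 3 or fewer counts at the lower time, and of some with up to 10, carry an exact 95% interval for counting error alone. The fitted changes of the other genes with 10 or fewer counts depend on the prior count. Reads were not tagged by molecule, so these intervals leave out amplification and biological spread.

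Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with time as the group, TMM factors were used (0.835 to 1.363), and 1 quasi-likelihood model with a mean per time was fitted to all 50 libraries, with 25 residual degrees of freedom. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05 over the 14793 genes tested and a log2 fold change of at least 1 in size. The common biological coefficient of variation was 0.237. Comparisons were each later time against 0 min, with 30, 60, 180 and 360 min described in full, 360 against 60 min, and each time against the one before. A joint test of all 24 differences from 0 min gave the genes that change over the course. Onset was the first of 2 successive times called in 1 direction, peak the time of the largest fitted change, and a gene had returned when its log2 change at 360 min was below 0.5 of that at its peak. Values are given as mean CPM ± SD with TMM-adjusted library sizes.

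32 gene lists of 646 members were tested as groups, with camera in limma 3.58.1 at its preset correlation of 0.01, on log2 CPM with a prior count of 2, for lists with 5 or more tested members. Benjamini-Hochberg adjustment covered 128 tests of lists and times against 0 min, and the lists at 360 against 60 min separately. Camera with a correlation estimated from the data was run beside it, and fry as a further test, which asks whether the genes of a list move 1 way on balance and compares them with no other gene. Counts adjusted over the list alone use the p of its members only.

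The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined, except for the tests and alternatives named below as chosen later. The rule names the 10 called genes with the largest change in each direction (5 at 15 min) among those with a mean of at least 5 CPM over the 4 libraries compared, with both libraries of one time above both of the other, leaving out predicted genes, clone names, and immunoglobulin and T cell receptor segments. Members of the fixed lists given as examples were chosen after their values were seen, mostly among those whose call does not hang on 1 library, and Myc, which is in no list, was also chosen after its values were seen.

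The method was tested on simulated data: of 100 genes planted at each size in a comparison of 60 with 0 min, edgeR recovered 61% at a log2 change of 1.5 and 79% at 3, with 4 calls among unchanged genes. DESeq2 1.42.0 recovered 66% and 83% with 18 such calls, and limma on log2(TPM + 1) 59% and 82% with 5. Of 100 genes planted with a lasting step of 3 log2 units at 90 min 88 were found, 85 of them at that time. Smaller or gradual rises were not planted for the onset. The simulated libraries were drawn independently, without a difference between replicate series, and most genes were left unchanged. These shares therefore need not hold for the real data.

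Whether the replicate numbers pair the libraries was checked over 6526 well-expressed genes: the deviation of replicate 1 from replicate 2 correlated between times with a median of 0.67 (0.31 to 0.91 over 300 pairs of times), so the replicate number was also fitted as a block. For the falls of red cell and macrophage genes, the difference between the extremes of a set was tested with edgeR standard errors, adjusted by the studentized range for the choice of those extremes. Exons shared with other expressed genes and identical 50-base sequences in their transcripts were counted for each named gene. Opposite exons of a gene with more counts also cover part of Fdft1 (18.3%), Csf1r (15.1%), H2-DMa (10.4%), Shmt1 (4.7%), Zfp961 (4.2%), Ccnd3 (4.1%) and Spns2 (3.2%). The other alternatives were DESeq2 size factors and library size as scaling, no low-count filter and a mean of at least 5 CPM, each replicate left out, only the 4 libraries compared, DESeq2 tests, limma on log2(TPM + 1) and log2(TPM + 0.1), no fold minimum and a log2 change of at least 2, adjustment pooled over the 24 times, a spline of time, and other onset rules. A replicate block together with an estimated correlation, and leaving out the library with the highest share of mitochondrial counts (5.06%) were added after seeing the data. Reads, transcript isoforms and unspliced RNA were not analysed here, and the values of some list members are not reported here. Figures were drawn with matplotlib 3.10.9.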

Results

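Transcript abundance was followed in mouse splenic B cells from the resting state through the first 6 hours of stimulation with anti-IgM, an antibody that crosslinks the B cell receptor. RNA was sequenced every 15 min from 0 to 360 min, which gave 25 time points with 2 biological replicates each, 50 libraries in all. The labels name the unstimulated cells of 0 min as the control, and each later group had received 10 µg/ml anti-IgM. The libraries held 14916063 to 20508138 expected counts, and 14793 genes had enough counts to be tested. The series holds no unstimulated library after 0 min, so a change against 0 min covers time in culture as well as anti-IgM.

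The 0 min libraries set the background for every comparison. Cd74, the invariant chain of MHC class II, stood at 11200 ± 3310 CPM (counts scaled to library size, given as mean ± SD, n = 2) and Cd79a, a signalling chain of the B cell receptor, at 2100 ± 604 CPM. Several immediate-early genes were already abundant before stimulation: Fos, a subunit of the AP-1 transcription factor, at 1530 ± 98.5 CPM, Jun, its partner, at 852 ± 73 CPM, and Klf6, a zinc finger transcription factor, at 1170 ± 121 CPM. Transcripts of other blood cells were present at lower levels, with Lyz2, lysozyme of macrophages and neutrophils, at 336 ± 69.6 CPM, C1qa, a complement gene of tissue macrophages, at 59.9 ± 35.7 CPM and Cd4 at 22.7 ± 2.46 CPM. The red cell globin gene Hbb-bs stood at a mean of 1070 CPM, and it shares 53.2% of its 50-base sequences with Hbb-bt, so the counts of each copy are uncertain.

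Over the whole course 8429 of the 14793 genes changed (57%; edgeR quasi-likelihood test of all 24 differences from 0 min, adjusted p under 0.05 and a largest change of at least 1 on the log2 scale). The response spread quickly. At 15 min 148 genes were higher and 6 lower than at 0 min, at 60 min 1623 were higher and 1409 lower, and by 120 min 2745 were higher and 2965 lower, near the final 3123 and 3629 at 360 min. The first principal component, which followed time, held 53.8% of the variance. The balance of higher to lower genes depends on the scaling, because removing the composition correction shifts all genes by -0.18, -0.35, -0.48 and -0.31 log2 units at 30, 60, 180 and 360 min. With library size alone the share of called genes that were higher was 56.4% at 30 min against 72.5%, 29.7% at 60 min against 53.5%, 29.9% at 180 min against 47.4%, and 36% at 360 min against 46.3%, so that at 60 min the larger group turns from higher to lower genes. It also turns with a replicate block (1726 higher and 1853 lower) and with limma on log2(TPM + 1) (799 and 1560) or log2(TPM + 0.1) (964 and 1947).

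**Figure D1:**
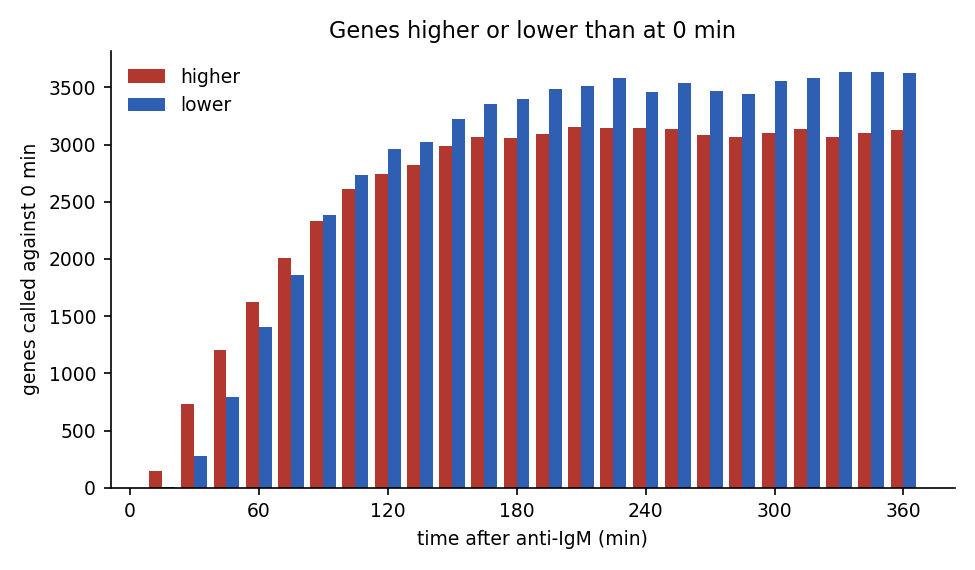
Number of genes higher (red) or lower (blue) than at 0 min at each of the 24 later times (min), in 2 libraries per time. The counts climb from 148 and 6 at 15 min to 2745 and 2965 at 120 min and end at 3123 and 3629; with library size as the only scaling the 60 min counts are 1029 higher and 2439 lower.

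At 15 min the response consisted almost wholly of rises. Nr4a3 (ENSMUSG00000028341.9, chromosome 4, 48045153 to 48086447, GRCm38), an orphan nuclear receptor induced by antigen receptor signals, rose from 32.4 ± 19.7 to 394 ± 116 CPM (n = 2 each; log2 change 3.60, adjusted p = 5.74e-06). Tgfb3, a cytokine of the TGF-beta family, rose by 2.88, Il1r2, a decoy receptor for interleukin 1, by 2.63, Pmepa1, an inhibitor of TGF-beta signalling, by 2.41, and Litaf, an endosomal protein, by 2.35 log2 units. The 3 lower genes that met the naming rule were Dusp7, a phosphatase of ERK (-1.25), the zinc finger gene Zfp961 (-1.08) and the orphan receptor gene Mrgpre (-1.07). Several of these calls are lost with fewer libraries, mostly with changes of similar size. Without unstimulated 0 min replicate 1 the log2 change was 2.87 for Tgfb3 (adjusted p = 0.0675), 2.76 for Il1r2 (0.0751), 2.10 for Pmepa1 (0.23), -1.03 for Dusp7 (0.0769), -0.94 for Zfp961 (0.0664) and -1.01 for Mrgpre (0.28). Without unstimulated 0 min replicate 2 it was 2.47 for Il1r2 (0.0577) and -1.14 for Mrgpre (0.136), and Mrgpre was also not called with library size alone (-1.19, adjusted p = 0.135) or with no low-count filter (-1.11, adjusted p = 0.394).

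The comparison of 30 with 0 min asked which genes change first. 730 genes were higher and 277 lower (edgeR quasi-likelihood). Nr4a3 led the rises at 1660 ± 478 CPM (log2 change 5.68), followed by Usp2, a deubiquitinase (4.96), Lmna, which encodes nuclear lamins A and C (4.83), Fosl1, an AP-1 subunit (4.72), and Lipg, a secreted lipase (4.69). Il1r2 (4.59), Tgfb3 (4.30), Cystm1 (4.05), Map9, a microtubule-associated protein (3.90), and Pmepa1 (3.89) completed the 10 largest rises. Among the falls, Klf2 (ENSMUSG00000055148.7, chromosome 8, 72319033 to 72321656), a transcription factor of lymphocyte quiescence, dropped from 1110 ± 299 to 222 ± 43.5 CPM (-2.32, adjusted p = 0.00127).

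The other large falls at 30 min were those of Fam78a (-2.54), Calhm2, a channel protein gene (-2.49), Prr12 (-2.43), Jun (-2.35), Rflnb, a filamin-binding protein (-2.35), Gpr146, an orphan receptor (-2.34), B3gnt8, a glycosyltransferase (-2.23), Sh2d3c, an adaptor protein (-2.17), and Zfp398, a zinc finger gene (-2.13). For 3 of these the call is lost when 1 library is left out, while the change stays large. Jun changed by -2.46 without anti-IgM 30 min replicate 1 (adjusted p = 0.0625) and by -2.34 without replicate 2 (0.0732), B3gnt8 by -1.99 without anti-IgM 30 min replicate 1 (0.0844), and Gpr146 by -1.94 without unstimulated 0 min replicate 1 (0.0548). Fosl1 is also uncertain, since 57.2% of its exon bases lie opposite exons of Ccdc85b and it is not stated whether counting used the strand. The same doubt holds for Calhm2 (10% opposite Pdcd11), B3gnt8 (18.1% opposite Bckdha) and Fam78a (3% opposite Nup214), whose partners have more counts than they do.

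Gene groups fixed in advance showed which parts of the cell moved by 30 min. Of 17 NF-kB subunits and inhibitors 6 were higher and none lower (7 higher when adjusted over the list alone, camera adjusted p = 2.57e-07, and adjusted p = 0.214 with an estimated correlation). Among them Rel, an NF-kB subunit of activated lymphocytes, rose by 1.74, its relative Relb by 1.34, the inhibitor Nfkbie by 1.34 and the adaptor Traf1 by 2.13 log2 units. With only the 4 libraries compared Rel is not called (adjusted p = 0.0553), nor is it with limma on log2(TPM + 1) (adjusted p = 0.081) or log2(TPM + 0.1) (adjusted p = 0.0987). Of 24 immediate-early genes 8 were higher and 3 lower (9 and 3 adjusted over the list alone, adjusted p = 0.00168, and adjusted p = 0.645 with an estimated correlation). The nuclear receptor Nr4a2 rose from 46.3 ± 0.125 to 484 ± 152 CPM, and the zinc finger factors Egr2, Egr3 and Klf10 rose by 1.45, 2.04 and 2.22. Of 19 cytokine and chemokine genes 10 were higher and 2 lower (12 and 2 adjusted over the list alone, adjusted p = 6.71e-05, and adjusted p = 0.426 with an estimated correlation). Tnfsf14, a ligand of the TNF family, rose by 2.92. Of 17 activation surface molecules 5 were higher and none lower (6 adjusted over the list alone, adjusted p = 0.000383, and adjusted p = 0.435 with an estimated correlation). The activation marker Cd83 rose from 1120 ± 406 to 3330 ± 449 CPM, the costimulatory ligand Cd86 by 1.84 and Il2ra, the interleukin 2 receptor alpha chain, by 2.34. Cd83 is not called with only the 4 libraries compared (adjusted p = 0.0678).

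Feedback, survival and metabolic genes moved in the same interval. Of 15 MAPK feedback regulators 6 were higher and 1 lower (the same counts adjusted over the list alone, adjusted p = 0.00814, and adjusted p = 0.426 with an estimated correlation). The inhibitor Spred2 rose by 1.34 (0.97 with limma on log2(TPM + 1), under the fold minimum) and the ERK phosphatase Dusp6 fell by 1.98. Of 7 anti-apoptotic BCL2 genes 4 were higher and none lower (4 adjusted over the list alone, adjusted p = 0.00772, and adjusted p = 0.29 with an estimated correlation). Bcl2l1, which encodes BCL-XL, rose by 1.95. The pro-apoptotic gene Bcl2l11, which encodes BIM, rose more, from 41.4 ± 2.93 to 392 ± 7.92 CPM (3.24). Of 22 cholesterol synthesis and uptake genes 8 were higher (8 adjusted over the list alone, adjusted p = 6.45e-08, and adjusted p = 0.242 with an estimated correlation). The synthesis enzymes Cyp51 (2.27), Hmgcs1 (1.93) and Sqle (1.73) rose. Of 40 ribosome biogenesis genes 8 were higher (8 adjusted over the list alone, adjusted p = 5.44e-11, and adjusted p = 0.37 with an estimated correlation). Nop58, a protein that guides rRNA methylation, rose by 1.44. Of 17 targets of the stress transcription factor ATF4 6 were higher (7 adjusted over the list alone, adjusted p = 1.2e-05, and adjusted p = 0.242 with an estimated correlation).

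The list of G1 cyclins and E2F activators also holds cell cycle inhibitors such as Cdkn1a and Cdkn1b, so its counts give no direction for cyclins alone. Of its 17 genes 2 were higher and 3 lower at 30 min (2 and 3 adjusted over the list alone, adjusted p = 0.0864, 0.0499 with a replicate block and 0.221 with a replicate block and an estimated correlation). The inhibitor Cdkn1a, which encodes p21, was among the higher ones (2.14). Of 27 DNA replication and mitosis genes 2 passed the adjusted p, with changes under the fold minimum (0 adjusted over the list alone, adjusted p = 0.813). Myc, a transcription factor of growth, rose from 517 to 1640 CPM (1.67, adjusted p = 3.82e-06). Of 24 quiescence and naive homing genes 3 were lower and 1 higher (the same adjusted over the list alone, adjusted p = 0.0485, and adjusted p = 0.473 with an estimated correlation, or 0.0557 with library size alone). Txnip, a thioredoxin inhibitor of resting cells, fell from 820 ± 1.3 to 229 ± 7.3 CPM. Fitting the replicate number as a block raised the genes lower at 30 min from 277 to 448.

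More genes differed from 0 min at 60 min than at 30 min. 1623 genes were higher and 1409 lower than at 0 min (edgeR quasi-likelihood). Chac1 (ENSMUSG00000027313.3, chromosome 2, 119351229 to 119354381), a glutathione-degrading enzyme and ATF4 target, rose from 0.117 ± 0.0401 to 45.3 ± 5.36 CPM (8.53, adjusted p = 1.24e-14). It had 5 counts at 0 min, which puts the ratio at 391 (95% counting interval 167 to 1210). Gng4, a G protein gamma subunit (7.66), Nr4a3 (6.52), Lipg (5.95), Trib3, a pseudokinase induced by ATF4 (5.88), Il1r1, the signalling receptor of interleukin 1 (5.78), Tnfsf4, the OX40 ligand (5.76), Il1r2 (5.54), Lmna (5.32) and Tnip3, an inhibitor of NF-kB signalling (5.31), followed.

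The largest falls at 60 min were those of Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273), which dropped from 1530 ± 98.5 to 101 ± 24.3 CPM (-3.92, adjusted p = 1.09e-05), B3gnt8 (-3.87), Klf2 (-3.79) and Psme2b (-3.56). Psme2b shares 68.7% of its 50-base sequences with the proteasome activator gene Psme2, so its counts are uncertain. Rflnb (-3.44), Calhm2 (-3.40), Fam78a (-3.30), Prr12 (-3.29), Sertad3, a transcriptional regulator (-3.23), and Ackr3, a scavenging chemokine receptor (-3.23), were also among the 10. Jun (-3.15), Klf6 (-2.31) and the ERK phosphatase Dusp6 (-2.67) fell as well. Without anti-IgM 60 min replicate 1, and with the remaining library assumed to vary like the other groups, 899 genes were lower instead of 1409.

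Genes for making ribosomes and charging tRNAs rose together at 60 min. Of 40 ribosome biogenesis genes 34 were higher and none lower (34 adjusted over the list alone, median 1.81, camera adjusted p = 1.55e-26, and adjusted p = 0.214 with an estimated correlation). Ncl, the nucleolar protein nucleolin, rose from 551 ± 117 to 2040 ± 284 CPM, Nop58 by 2.65 and Nolc1, a nucleolar scaffold, by 2.55. Of 20 cytosolic aminoacyl-tRNA synthetases 13 were higher (13 adjusted over the list alone, adjusted p = 2.9e-08, and adjusted p = 0.319 with an estimated correlation). Aars rose by 2.87 and Cars by 2.76. Of 17 ATF4 targets 11 were higher (11 adjusted over the list alone, adjusted p = 3.59e-09, and adjusted p = 0.214 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, rose by 3.48. Of 22 cholesterol genes 14 were higher (14 adjusted over the list alone, adjusted p = 1.68e-07, and adjusted p = 0.242 with an estimated correlation), and of 24 purine and pyrimidine synthesis genes 6 were (6 adjusted over the list alone, adjusted p = 0.0047, and adjusted p = 0.606 with an estimated correlation). Ctps, CTP synthase, rose by 2.19. The cationic amino acid transporter gene Slc7a1, also in the ATF4 list, rose by 3.20. With library size alone 8 cholesterol genes were higher instead of 14, and 2 nucleotide synthesis genes were lower instead of 0. Myc stood at 2540 CPM (2.30).

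Several signalling and activation lists were called at 60 min. Of the 24 immediate-early genes 9 were higher and 6 lower (9 and 6 adjusted over the list alone, adjusted p = 0.148, and 0.0263 by fry). Their median log2 change was 0.37 at 60 min and 0.43 at 30 min (0.02 and 0.26 with library size alone), and the list was not tested between these times. Of the NF-kB genes 9 were higher (9 adjusted over the list alone, adjusted p = 6.43e-06, and adjusted p = 0.242 with an estimated correlation). Rel rose by 2.03 and the inhibitor Nfkbid from 318 ± 7.68 to 1770 ± 43.7 CPM. Of the activation surface molecules 11 were higher and 1 lower (11 and 1 adjusted over the list alone, adjusted p = 4.66e-05, and adjusted p = 0.37 with an estimated correlation). Il2ra rose by 4.92, Slc7a5, an amino acid transporter of that list, by 3.92 and Cd86 by 3.25. Of the cytokine genes 12 were higher and 2 lower (12 and 2 adjusted over the list alone, adjusted p = 0.00145, and adjusted p = 0.536 with an estimated correlation). The chemokines Ccl3 and Ccl4 rose by 2.69 and 3.43. The transcription factor Irf4, a regulator of B cell differentiation, rose by 1.85, Prdm1, a plasma cell regulator, by 2.04, and Nfatc1, a calcium-responsive factor, by 2.33. Of 20 B cell fate transcription factors 6 were higher and 1, Bcl6, a germinal centre factor, lower (6 and 1 adjusted over the list alone, adjusted p = 0.653). Scaled by library size alone, 3 fate factors were higher and 3 lower, and 2 activation surface molecules were lower instead of 1.

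Further lists were also called at 60 min. The MAPK feedback list had 8 higher and 2 lower members (8 and 2 adjusted over the list alone, adjusted p = 0.0275, and adjusted p = 0.509 with an estimated correlation). The phosphatase Dusp4 rose by 1.76. The anti-apoptotic list had 4 higher and 1 lower member (4 and 1 adjusted over the list alone, adjusted p = 0.0385, 0.0728 with a replicate block and adjusted p = 0.426 with an estimated correlation). Bcl2l1 rose by 3.60. Of 31 proteasome subunits 3 were higher (3 adjusted over the list alone, adjusted p = 2.84e-05, and adjusted p = 0.645 with an estimated correlation), and of 20 heat shock and chaperonin genes 3 were higher and 1 lower (3 and 2 adjusted over the list alone, adjusted p = 0.0413, and adjusted p = 0.863 with an estimated correlation). Of the quiescence genes 7 were lower and 1 higher (8 and 1 adjusted over the list alone, adjusted p = 0.0217, and adjusted p = 0.426 with an estimated correlation). Scaled by library size alone, 0 proteasome subunits were higher instead of 3, 2 heat shock and chaperonin genes were higher and 2 lower, and 12 quiescence genes were lower instead of 7. Cdkn1b, an inhibitor of the cell cycle kinases, fell by 1.59 and Cd79b, a receptor signalling chain, by 2.01, and Ciita, the regulator of MHC class II genes, fell by 1.92.

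**Figure D2:**
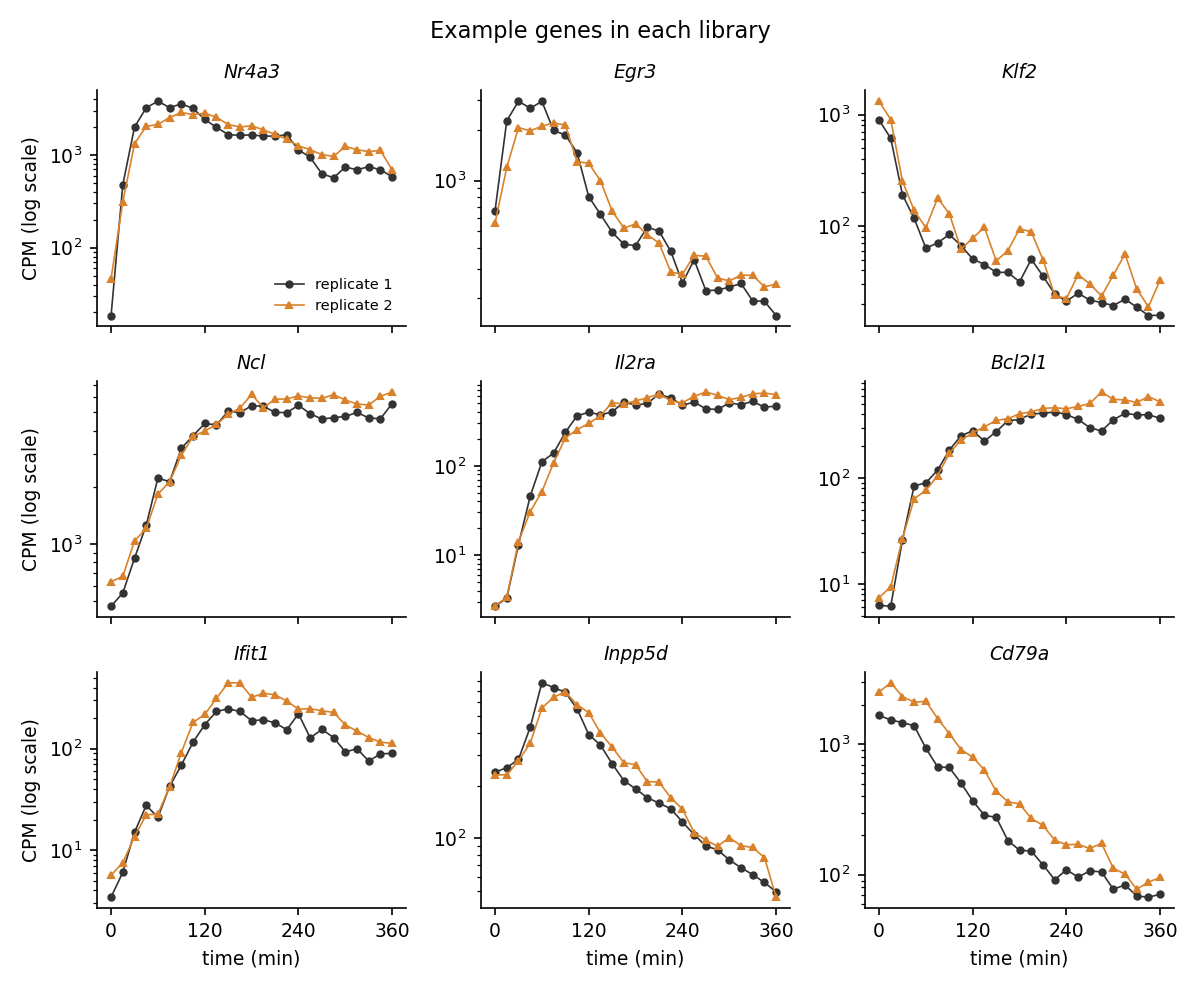
Abundance of 9 genes in each library, in CPM on a log axis against time in min, with 1 line per replicate. Nr4a3 and Egr3 rise early and later decline, Klf2 and Cd79a fall, Ncl, Il2ra and Bcl2l1 rise and stay high, Ifit1 is higher from 30 min on and later declines, and Inpp5d is higher at 60 min (667 CPM) and lower at 360 min (47.8 CPM) than at 0 min (235 CPM).

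By 180 min most or all members of the ribosome biogenesis, tRNA synthetase and nucleotide synthesis lists were higher, and so were most interferon-stimulated genes. 3056 genes were higher and 3398 lower than at 0 min (edgeR quasi-likelihood; 1960 and 4600 with library size alone). Il2ra (ENSMUSG00000026770.5, chromosome 2, 11642807 to 11693193) rose from 2.68 ± 0.0274 to 506 ± 41.3 CPM (7.56, adjusted p = 1.62e-15), and Gng4 reached 269 ± 29.1 CPM from 7 counts at 0 min, a ratio of 1660 (95% counting interval 807 to 4140). Chac1 (8.56), Ramp3, a receptor-modifying protein (7.59), Lrrc32, the docking protein of latent TGF-beta (6.58), Slc1a4, a neutral amino acid transporter (6.57), Trib3 (6.52) and Slc7a3, a cationic amino acid transporter (6.39), were also among the largest rises. Gpnmb, a membrane glycoprotein, and Plagl1, a zinc finger factor, had 1 and 2 counts at 0 min, and their ratios were 670 (120 to 26500) and 524 (145 to 4330).

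The largest falls at 180 min were those of B3gnt8 (-6.97), Pglyrp2, a peptidoglycan hydrolase (-6.19), Emid1 (-6.06), the adhesion molecule gene Ceacam1 (-5.94), Map2k6, a kinase upstream of p38 (-5.91), March1, a ubiquitin ligase that removes MHC class II and CD86 from the cell surface (-5.83), Cacna1i, a calcium channel subunit (-5.72), Fos (-5.70), Zfp831 (-5.66) and Gfra2, a growth factor coreceptor (-5.64). Ceacam1 shares 29.7% of its 50-base sequences with other genes, mostly Ceacam2. Cd22, an inhibitory coreceptor, fell from 722 ± 82.9 to 27.9 ± 11.2 CPM and Cd79a from 2100 ± 604 to 251 ± 137 CPM.

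Of 40 ribosome biogenesis genes all 40 were higher at 180 min (40 adjusted over the list alone, median 3.12, adjusted p = 3.46e-26, and adjusted p = 0.214 with an estimated correlation). Rrp1b, an rRNA processing factor, rose by 4.02 and Polr1b, an RNA polymerase I subunit, by 3.90. Of 20 tRNA synthetases 18 were higher (18 adjusted over the list alone, adjusted p = 7.4e-11, and adjusted p = 0.242 with an estimated correlation). Cars rose by 4.13 and Lars by 3.63. Of 24 nucleotide synthesis genes 20 were higher and 2 lower (20 and 2 adjusted over the list alone, adjusted p = 2.77e-08, and adjusted p = 0.242 with an estimated correlation). Ctps rose by 4.15, the folate enzyme gene Shmt1 by 4.32 and Gart, a purine enzyme, by 2.58. Of 17 ATF4 targets 14 were higher (14 adjusted over the list alone, adjusted p = 4.57e-09, and adjusted p = 0.214 with an estimated correlation). Asns, asparagine synthetase, rose by 6.05, the serine enzyme gene Psat1 by 4.60 and Shmt2 by 3.98. The cytosolic ribosomal proteins themselves moved little: of 76 genes Rps12 alone was higher (1.58) and none lower (0 adjusted over the list alone, adjusted p = 0.156, 0.000156 with a replicate block and 0.766 with a replicate block and an estimated correlation). The call of Rps12 is lost without unstimulated 0 min replicate 1 (1.03, adjusted p = 0.308), without anti-IgM 180 min replicate 1 (0.56, adjusted p = 0.542) and with library size alone (1.20, adjusted p = 0.124), and 19.3% of its 50-base sequences occur in Rps12-ps3, which has more counts. Their medians of 0.11, 0.32, 0.54 and 0.28 at 30, 60, 180 and 360 min become -0.06, -0.03, 0.05 and -0.02 with library size alone.

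Most interferon-stimulated genes were higher by 180 min. Of 23 such genes 21 were higher at 180 min and none lower (21 adjusted over the list alone, adjusted p = 4.93e-08, and adjusted p = 0.26 with an estimated correlation), whereas at 60 min 4 were higher and 4 lower (the same adjusted over the list alone, adjusted p = 0.396). Ifit1, an RNA-binding antiviral protein, stood at 4.55 ± 1.58 CPM at 0 min, 14.3 ± 1 CPM at 30 min, 21.9 ± 1.14 CPM at 60 min and 101 ± 16.2 CPM at 360 min, and its log2 change at 180 min was 5.80. Rsad2, which encodes viperin, rose by 5.72, the ubiquitin-like Isg15 by 4.61 and the transcription factor Irf7 by 2.93. Proteasome subunits rose too, with 25 of 31 higher (25 adjusted over the list alone, adjusted p = 5.59e-09, and adjusted p = 0.473 with an estimated correlation). Psmd11 rose by 2.67. Of 20 heat shock and chaperonin genes 13 were higher and 1 lower (13 and 2 adjusted over the list alone, adjusted p = 0.000646, and adjusted p = 0.645 with an estimated correlation). The mitochondrial chaperones Hspa9 and Hspd1 rose by 3.40 and 2.37. Scaled by library size alone, 16 proteasome subunits were higher instead of 25, 6 interferon-stimulated genes were lower at 60 min instead of 4, and 2 heat shock and chaperonin genes were lower instead of 1.

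Cell cycle genes split at 180 min. In the mixed list of 17 G1 cyclins, E2F activators and cell cycle inhibitors 4 were higher and 9 lower (4 and 9 adjusted over the list alone, adjusted p = 0.282). Ccnd2 rose by 3.48 and the kinases Cdk6 and Cdk4, partners of D-type cyclins, by 3.06 and 1.94, while Ccnd3 fell by 2.52. Of 27 DNA replication and mitosis genes 3 were higher and 13 lower (3 and 13 adjusted over the list alone, adjusted p = 0.0666, 0.0142 with library size alone, 0.863 with an estimated correlation and 0.474 with a replicate block and an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 2.20 and Ccnb2, a mitotic cyclin, by 2.85. Of 18 genes of glycolysis and glucose or lactate transport 9 were higher and 2 lower (9 and 2 adjusted over the list alone, adjusted p = 0.0888, 0.0297 with a replicate block, 0.483 with a replicate block and an estimated correlation, and 0.0418 with library size alone). Hexokinase Hk2 rose by 2.96, lactate dehydrogenase Ldha by 2.68 and the lactate transporter Slc16a1 by 2.39. With library size alone the counts were 0 higher and 19 lower for DNA replication and mitosis and 6 higher and 4 lower for glycolysis. The transferrin receptor Tfrc rose by 3.67, Bcl2l1 by 5.80, the AP-1 factor Batf by 3.64 and Nfkb1 by 2.81. NF-kB genes (11 higher, 11 adjusted over the list alone, adjusted p = 0.00168, and adjusted p = 0.426 with an estimated correlation), activation surface molecules (11 higher and 1 lower, the same adjusted over the list alone, adjusted p = 0.000847, and adjusted p = 0.45 with an estimated correlation) and cytokine genes (13 higher and 2 lower, the same adjusted over the list alone, adjusted p = 0.00403, and adjusted p = 0.604 with an estimated correlation) remained above other genes. Of the NF-kB genes 8 were higher and 1 lower with library size alone.

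B cell receptor and identity genes were among those lower at 180 min. Of 25 B cell receptor signalling components 9 were lower and 4 higher (9 and 4 adjusted over the list alone, adjusted p = 0.00961, and adjusted p = 0.45 with an estimated correlation). The kinase Syk fell by 2.96. Of 20 B lineage identity genes 12 were lower and none higher (12 adjusted over the list alone, adjusted p = 0.00403, and adjusted p = 0.645 with an estimated correlation), and of 24 quiescence genes 16 were lower and 2 higher (16 and 2 adjusted over the list alone, adjusted p = 0.00012, and adjusted p = 0.214 with an estimated correlation). Foxo1, a transcription factor of resting lymphocytes, fell by 2.04, Rasgrp2, an exchange factor of integrin activation, by 4.16 and Klf2 by 4.14. Of the quiescence genes 1 was higher instead of 2 with library size alone. Markers of monocytes, macrophages and neutrophils fell beside them, with 10 of 15 lower and 1 higher (10 and 1 adjusted over the list alone, adjusted p = 0.00814, and adjusted p = 0.45 with an estimated correlation). The share of counts in immunoglobulin genes was 1.58% and 1.95% in the 0 min libraries and 0.3% and 0.35% in the 360 min libraries.

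**Figure D3:**
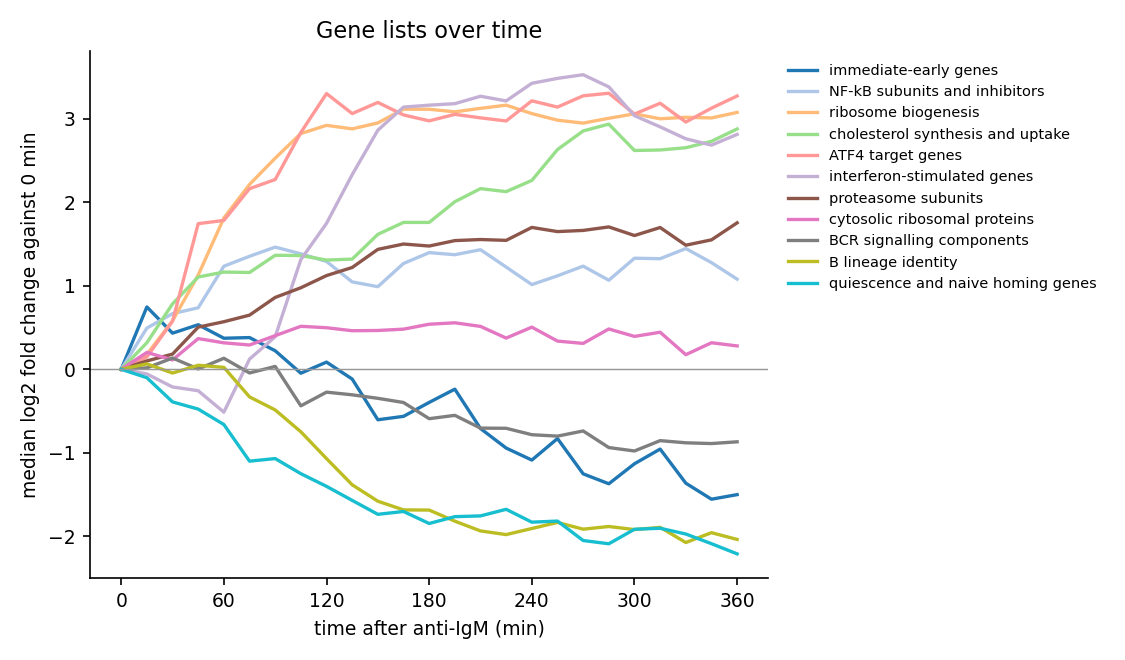
Median log2 fold change against 0 min of the tested members of 11 gene lists, over time in min. Ribosome biogenesis reaches 3.12 at 180 min, interferon-stimulated genes stand at -0.51 at 60 min and 3.17 at 180 min, and B lineage identity reaches -2.04 at 360 min; with library size alone the 60 min medians change sign for cytosolic ribosomal proteins (0.32 to -0.03), B lineage identity (0.02 to -0.33) and B cell receptor signalling (0.13 to -0.22), and so do the 30 min medians of the first and the last and the 360 min median of the first.

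At 360 min most or all genes of the ribosome biogenesis, tRNA synthetase and nucleotide synthesis lists were higher than at 0 min. Most of the quiescence and B lineage identity lists were lower. 3123 genes were higher and 3629 lower than at 0 min (edgeR quasi-likelihood). Bcat1 (ENSMUSG00000030268.17, chromosome 6, 144993835 to 145076184), a transaminase of branched-chain amino acids, rose from 0.866 ± 0.403 to 123 ± 8.34 CPM (7.13, adjusted p = 1.93e-17), and Il2ra (7.67), Slc7a3 (7.15), Trib3 (6.98), Slc1a4 (6.94), Ramp3 (7.78), Chac1 (9.04) and Gng4 (9.95) were among the largest rises, with Sytl3 (6.69), 21.1% of whose 50-base sequences occur in other genes. Gpnmb stood at 484 counts against 1, a ratio of 544 (97.2 to 21500). Cacna1i (ENSMUSG00000022416.15, chromosome 15, 80287238 to 80398279) fell furthest, from 128 ± 22.9 to 0.181 ± 0.0244 CPM (-9.40, adjusted p = 1.02e-12), a ratio of 697 from 7 counts (338 to 1730).

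The 10 largest falls at 360 min included several genes with few counts left. Cd163, a haemoglobin scavenger receptor of macrophages, fell to 3 counts, a ratio of 205 (69.7 to 994); Fcgrt, the neonatal Fc receptor, to 3 counts (485; 166 to 2360); Ptgs1, cyclooxygenase 1, to 1 count (429; 76.6 to 17000); and Hpgd, a prostaglandin-degrading enzyme, to 2 counts (333; 92 to 2760). Abcc3, a membrane transporter (310; 85.5 to 2560), Adamdec1, a metalloprotease-like protein (231; 63.6 to 1910), C6, a complement component (226; 62.3 to 1870), and Emid1 (388; 107 to 3210) each fell to 2 counts, and Srpk3, a kinase, fell by 7.46 log2 units. In the fixed lists 14 of 15 monocyte, macrophage and neutrophil markers were lower (14 adjusted over the list alone, adjusted p = 2.66e-05, and adjusted p = 0.242 with an estimated correlation). Csf1r, the receptor for macrophage growth factor, fell from 155 ± 60.4 to 4.7 ± 3.1 CPM and Lyz2 changed by -3.80 log2 units. Cd14 was higher (1.53), a call that is lost without anti-IgM 360 min replicate 1 (0.40, adjusted p = 0.349) and with limma on log2(TPM + 1) (adjusted p = 0.0612).

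Further marker lists were tested at 360 min. Of 11 erythroid and platelet markers 10 were lower (10 adjusted over the list alone, adjusted p = 0.000694, and adjusted p = 0.333 with an estimated correlation). Hbb-bs stood at 236 ± 106 CPM, and Alas2, the first enzyme of red cell haem synthesis, fell by 3.64. Of 10 NK cell markers 6 were lower (6 adjusted over the list alone, adjusted p = 0.0305, 0.0616 with library size alone and adjusted p = 0.45 with an estimated correlation). Among them Klrd1 fell by 4.21. Of 10 dendritic cell markers 7 were lower and 2 higher (7 and 2 adjusted over the list alone, adjusted p = 0.0413, and adjusted p = 0.249 with an estimated correlation). The integrin gene Itgax changed by -5.66 and the transcription factor gene Zbtb46 by 2.29. Of 14 T cell markers 3 were lower (3 adjusted over the list alone, adjusted p = 0.25). Cd4 (-4.85) and Cd8a (-2.86) fell. Of 11 plasma cell markers 6 were lower (7 adjusted over the list alone, adjusted p = 0.114, 0.0214 with a replicate block and 0.221 with a replicate block and an estimated correlation). Derl3, a protein of the secretory pathway, fell by 2.60. Of 10 marginal zone B cell markers 5 were lower (5 adjusted over the list alone, adjusted p = 0.0666, 0.0316 with a replicate block, 0.221 with a replicate block and an estimated correlation, and 0.0347 with library size alone). Mzb1 (-3.43) and Tm6sf1 (-5.73) fell.

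**Figure D4:**
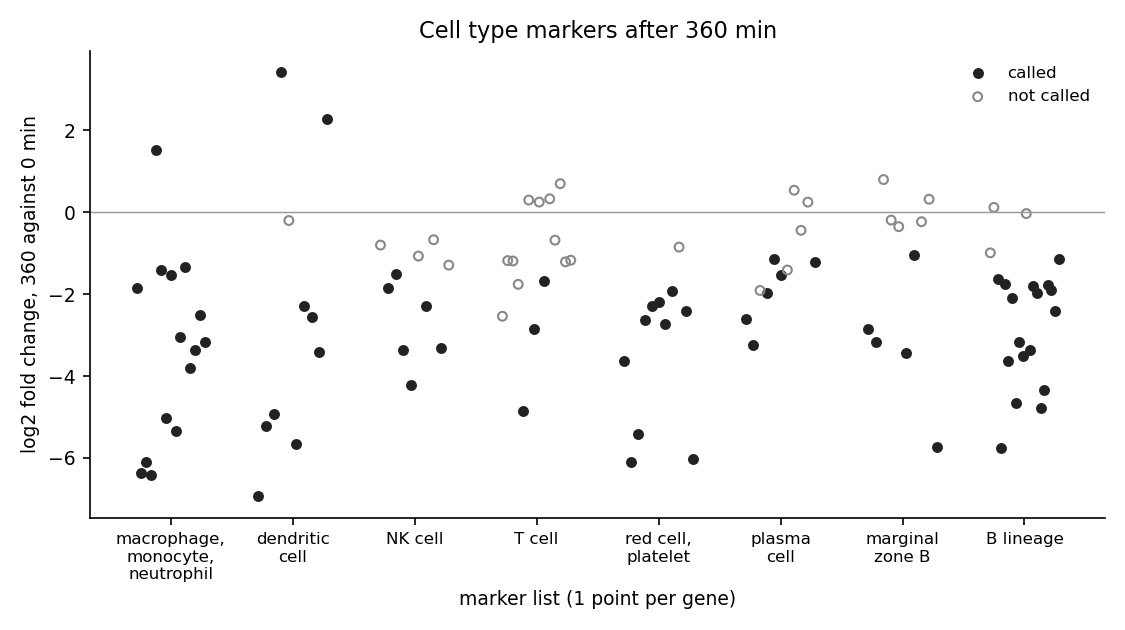
Log2 fold change at 360 min against 0 min of each tested marker gene, by list; filled points passed the test (adjusted p under 0.05 and a change of at least 1) and open points did not. 14 of 15 macrophage, monocyte and neutrophil markers, 10 of 11 red cell and platelet markers and 17 of 20 B lineage identity genes were lower.

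Most B lineage genes were lower at 360 min. Of 20 B lineage identity genes 17 were lower and none higher (17 adjusted over the list alone, adjusted p = 7.1e-07, and adjusted p = 0.37 with an estimated correlation). Cd79a fell to 83 ± 17.4 CPM (-4.66), Cd22 by 5.76, Pax5, the B lineage commitment factor, by 2.41, Ciita by 3.51 and H2-DMa, a chaperone of MHC class II peptide loading, by 4.79. Cd74 and H2-Aa, a class II chain, fell by 2.10 and 1.81 but remained at 2630 ± 743 and 1370 ± 203 CPM. Of 24 quiescence and naive homing genes 20 were lower and 1 higher (20 and 1 adjusted over the list alone, adjusted p = 1.68e-07, and adjusted p = 0.214 with an estimated correlation). Klf2 fell by 5.52 and the egress receptor S1pr1 by 4.27. Of the receptor signalling components 11 were lower and 1 higher (11 and 1 adjusted over the list alone, adjusted p = 0.000101, and adjusted p = 0.242 with an estimated correlation). Of 20 fate transcription factors 12 were lower and 5 higher (12 and 5 adjusted over the list alone, adjusted p = 0.168). With library size alone 15 receptor signalling components were lower and 0 higher, and 0 quiescence genes were higher instead of 1. Batf (4.77) and Id2 (2.43) rose and Ikzf3, a factor of mature lymphocytes, fell by 3.13.

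Biosynthesis stayed high at 360 min. All 40 ribosome biogenesis genes were higher (40 adjusted over the list alone, adjusted p = 3.19e-24, and adjusted p = 0.214 with an estimated correlation), with Ncl at 5980 ± 594 CPM. Of 22 cholesterol genes 19 were higher (19 adjusted over the list alone, adjusted p = 8.39e-10, and adjusted p = 0.214 with an estimated correlation). Idi1 and Sqle rose by 4.09 each and the synthesis enzyme gene Fdft1 by 3.68. Of 31 proteasome subunits 29 were higher (29 adjusted over the list alone, adjusted p = 5.44e-11, and adjusted p = 0.426 with an estimated correlation). Psmd7 rose by 2.73. Of 20 heat shock and chaperonin genes 16 were higher (16 adjusted over the list alone, adjusted p = 0.000121, and adjusted p = 0.606 with an estimated correlation). Cct6a rose by 3.09, and Hspd1, which shares 38% of its 50-base sequences with other genes, by 2.94. With library size alone 15 heat shock and chaperonin genes were higher and 1 lower. Of 18 glycolysis genes 11 were higher and 2 lower (11 and 2 adjusted over the list alone, adjusted p = 0.0385, and adjusted p = 0.777 with an estimated correlation). Ldha rose by 2.75. The tRNA synthetases (18 of 20 higher, 18 adjusted over the list alone, adjusted p = 3.04e-10, and adjusted p = 0.242 with an estimated correlation) and the nucleotide synthesis genes (20 of 24 higher and 2 lower, the same adjusted over the list alone, adjusted p = 2.98e-08, and adjusted p = 0.242 with an estimated correlation) also remained above other genes, with Cad at 2.49. So did the ATF4 targets (14 of 17 higher, 15 adjusted over the list alone, adjusted p = 1.58e-08, and adjusted p = 0.214 with an estimated correlation) and the interferon-stimulated genes (20 of 23 higher, 20 adjusted over the list alone, adjusted p = 7.75e-07, and adjusted p = 0.328 with an estimated correlation).

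Survival, secretory and early genes completed the picture at 360 min. Bcl2l1 rose by 6.02 to 448 ± 112 CPM and Bcl2 fell by 2.85, and 4 of the 7 anti-apoptotic genes were higher and 1 lower (4 and 1 adjusted over the list alone, adjusted p = 0.379). Of 8 pro-apoptotic genes 3 were higher and 3 lower (3 and 3 adjusted over the list alone, adjusted p = 0.653), with Bax (1.74) and Bid (1.34, not called with limma on log2(TPM + 1), adjusted p = 0.0554) up and Pmaip1, which encodes NOXA, down (-2.69). Of 15 endoplasmic reticulum chaperones 2 were higher and 2 lower (2 and 2 adjusted over the list alone, adjusted p = 0.792). The lectin chaperone Canx rose by 1.37. Hspa5, the main stress-induced chaperone, was at 934 ± 220 CPM at 0 min and 1770 ± 503 CPM at 360 min (adjusted p = 0.0518), and it was called without anti-IgM 360 min replicate 1 (1.17, adjusted p = 0.0404). Of 24 immediate-early genes 14 were lower and 3 higher (14 and 3 adjusted over the list alone, adjusted p = 0.0196, and adjusted p = 0.79 with an estimated correlation). With library size alone 3 anti-apoptotic genes were higher and 2 lower, and 1 chaperone of the endoplasmic reticulum was higher and 3 lower. Btg2, an antiproliferative factor, fell by 3.34. The MAPK feedback list had 6 higher and 6 lower members (6 and 6 adjusted over the list alone, adjusted p = 0.89). The phosphatase Dusp1 fell by 3.89. NF-kB genes (10 higher, 10 adjusted over the list alone, adjusted p = 0.0157, and adjusted p = 0.533 with an estimated correlation), activation surface molecules (10 higher and 3 lower, the same adjusted over the list alone, adjusted p = 0.0117, and adjusted p = 0.606 with an estimated correlation) and cytokine genes (12 higher and 2 lower, the same adjusted over the list alone, adjusted p = 0.02, and adjusted p = 0.67 with an estimated correlation) kept their position, with the chemokine Ccl22 up by 5.51. Of the NF-kB genes 7 were higher and 1 lower with library size alone.

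Genes of the cell cycle remained mixed at 360 min. Ccnd2 reached 1230 ± 278 CPM (4.08) and Cdk4 rose by 2.25, while Cdkn1b fell by 2.46. In the mixed list of 17 G1 cyclins, E2F activators and cell cycle inhibitors 4 were higher and 6 lower (4 and 6 adjusted over the list alone, adjusted p = 0.394). Of 27 DNA replication and mitosis genes 2 were higher and 12 lower (2 and 12 adjusted over the list alone, adjusted p = 0.132). Scaled by library size alone, 0 of the replication and mitosis genes were higher and 15 lower. The proliferation marker Mki67 fell by 1.11 and Ccnb2 by 3.14. None of the 13 mitochondrially encoded mRNAs was called at 30, 60, 180 or 360 min (0 adjusted over the list alone, adjusted p = 0.715 at 360 min). With library size alone 2 of them were lower at 180 min. Of 76 ribosomal protein genes Rps2 alone was higher (0 adjusted over the list alone, adjusted p = 0.502, 0.0487 with a replicate block and 0.877 with a replicate block and an estimated correlation). Its change of 1.29 was 0.99 with library size alone and 0.88 without unstimulated 0 min replicate 1 (adjusted p = 0.125), where it is not called, and 43% of its 50-base sequences occur in other genes.

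Of the 128 list tests against 0 min 59 were called by camera with its preset correlation, and none was called with an estimated correlation, where the smallest adjusted p was 0.214. No list's median, mean and test differed in sign where it was called; among the 160 tests that include 360 against 60 min, 14 tests that were not called had such a difference.

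The comparison of 360 with 60 min asked how the late state differs from the early response. 2180 genes were higher at 360 min and 2839 lower (edgeR quasi-likelihood). Slc6a9 (ENSMUSG00000028542.17, chromosome 4, 117834506 to 117875198), a glycine transporter, rose from 0.628 ± 0.294 to 55 ± 5.27 CPM (6.43, adjusted p = 2.5e-09). Other large rises were those of Slc7a3 (5.96), Cth, an enzyme of cysteine synthesis (5.10), Bcat1 (4.59), Pycr1, an enzyme of proline synthesis (4.41), Usp18, which removes ISG15 from proteins (5.12), Oas3, an antiviral enzyme (5.02), and Ifi47, an interferon-inducible GTPase (4.65). Olfr56 (6.37) shares 111 exon bases with Ifi47 on the same strand, so its count is uncertain. Alpl, alkaline phosphatase, rose by 4.41.

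The largest falls from 60 to 360 min were those of Cacna1i (-8.23), Srpk3 (-7.76), Fry (-7.53), Usp2 (-6.58), Itgb7, a homing integrin (-6.37), Cyp4f18, a lipid oxidase (-6.22), Spns2, an exporter of sphingosine 1-phosphate (-6.15), and Mrc1, the mannose receptor of macrophages (-5.95). Fcgrt fell to 3 counts, a ratio of 213 (72.4 to 1030), and Pde2a, a phosphodiesterase, also to 3 counts (141; 48 to 688). Pde2a shares 64.3% of its exon bases with a predicted gene on the same strand, and its call (adjusted p = 0.0456) is lost when any 1 of the 4 libraries is left out, with an adjusted p of 0.0888 and 0.058 without anti-IgM 60 min replicates 1 and 2 and of 0.171 and 0.18 without anti-IgM 360 min replicates 1 and 2, although the fitted change stays between -6.70 and -7.51.

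Interferon-stimulated genes were higher at 360 than at 60 min in 22 of 23 cases (22 adjusted over the list alone, camera adjusted p = 6.82e-11, and adjusted p = 0.173 with an estimated correlation). Irf7 rose by 3.31, Ifit1 by 2.21 and the signalling factor Stat2 by 2.98. Of 22 cholesterol genes 12 were higher (12 adjusted over the list alone, adjusted p = 2.52e-07, and adjusted p = 0.173 with an estimated correlation). Fdps (2.50) and Mvd (2.04) rose. Ribosome biogenesis (28 of 40 higher, 28 adjusted over the list alone, adjusted p = 6.76e-14, and adjusted p = 0.173 with an estimated correlation) and nucleotide synthesis (18 of 24 higher and 2 lower, the same adjusted over the list alone, adjusted p = 1.62e-08, and adjusted p = 0.173 with an estimated correlation) rose further, with Gart up by 2.39. Proteasome subunits (19 of 31 higher, 19 adjusted over the list alone, adjusted p = 1.22e-09, and adjusted p = 0.315 with an estimated correlation) rose as well. So did tRNA synthetases (12 of 20 higher, 12 adjusted over the list alone, adjusted p = 1.25e-07, and adjusted p = 0.211 with an estimated correlation), heat shock and chaperonin genes (14 of 20, 14 adjusted over the list alone, adjusted p = 4.06e-05, and adjusted p = 0.377 with an estimated correlation), glycolysis genes (11 of 18, 11 adjusted over the list alone, adjusted p = 0.0124, and adjusted p = 0.502 with an estimated correlation) and ATF4 targets (8 of 17 higher and 1 lower, the same adjusted over the list alone, adjusted p = 0.00724, and adjusted p = 0.323 with an estimated correlation). Shmt2 rose by 3.56 and Asns by 3.30.

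The genes that fell between 60 and 360 min held much of the early response and of the B cell programme. Of 24 immediate-early genes 17 were lower (17 adjusted over the list alone, adjusted p = 1.05e-06, and adjusted p = 0.276 with an estimated correlation). Egr3 fell by 3.66 and Nr4a2 by 4.11. Of 15 MAPK feedback regulators 6 were lower and 1 higher (6 and 1 adjusted over the list alone, adjusted p = 0.0204, and adjusted p = 0.324 with an estimated correlation). The phosphatase Dusp2 changed by -2.70 and Spred2 by -3.06. Of 20 B lineage identity genes 18 were lower (18 adjusted over the list alone, adjusted p = 4.37e-09, adjusted p = 0.173 with an estimated correlation, and 0.0109 with a replicate block and an estimated correlation). Cd79a (-4.21) and Cd22 (-4.76) fell, and so did the IgE receptor gene Fcer2a of the quiescence list (-2.43). Of 25 receptor signalling components 17 were lower (17 adjusted over the list alone, adjusted p = 1.19e-07, and adjusted p = 0.131 with an estimated correlation). Syk fell by 2.18 and Inpp5d, which encodes the inhibitory phosphatase SHIP1, changed by -3.80. Of 24 quiescence genes 18 were lower (18 adjusted over the list alone, adjusted p = 2.74e-08), and this is the call of the 22 in this comparison that holds with an estimated correlation (adjusted p = 0.0455). With a replicate block and an estimated correlation 3 calls hold: quiescence (adjusted p = 0.00722), B lineage identity and marginal zone markers (0.0334). Of the 10 marginal zone markers 5 were lower (5 adjusted over the list alone, adjusted p = 0.00768, and adjusted p = 0.173 with an estimated correlation). Of 20 fate transcription factors 11 were lower and 3 higher (11 and 3 adjusted over the list alone, adjusted p = 0.013, and adjusted p = 0.323 with an estimated correlation). Markers of macrophages (12 of 15 lower, 12 adjusted over the list alone, adjusted p = 2.4e-06, and adjusted p = 0.173 with an estimated correlation) and of red cells and platelets (11 of 11 lower, 11 adjusted over the list alone, adjusted p = 0.00014, and adjusted p = 0.173 with an estimated correlation) fell over the same interval. Also lower were 7 of 10 NK cell, 7 of 10 dendritic cell (1 higher), 5 of 14 T cell and 5 of 11 plasma cell markers.

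Many genes kept their direction from 60 to 360 min. Of the 1623 genes higher at 60 min 1116 were also higher at 360 min (68.8%; 342.6 expected for independent sets) and 58 were lower; of the 1409 lower at 60 min 970 were also lower at 360 min (68.8%; 345.7 expected) and 53 were higher. Both comparisons use the same 0 min libraries, which by itself can add to the overlap. In 10 simulations with no gene changed at either time the highest overlap was 0 in each direction, with at most 3 genes called. With so few calls an overlap could hardly arise, so its absence decides nothing about the shared libraries. What the shared libraries add for genes that change at only 1 of the times was not tested. Among the genes higher at 60 min 375 were lower and 322 higher at 360 than at 60 min.

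The 15 min spacing placed most first changes in the first 2 hours. 4020 genes rose and 4606 fell with an onset, defined as the first of 2 successive times at which a gene was called, and 127 did both. The median onset was 75 min for rising and 90 min for falling genes. Of the 141 genes with an onset at 15 min, a group that includes Nr4a3, Usp2 and Tgfb3, 48.9% had returned below 0.5 of their peak log2 rise by 360 min, compared with 16.8% of all rising genes. A later onset leaves less time to return by 360 min, so these shares are not measured alike. Between 30 and 150 min replicate 1 libraries lay ahead of replicate 2 libraries by a median of 8.9 min. Peak times were loose, since they differed between the replicate series by a median of 45 min and lay within 30 min of each other for 46.2% of rising genes.

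**Figure D5:**
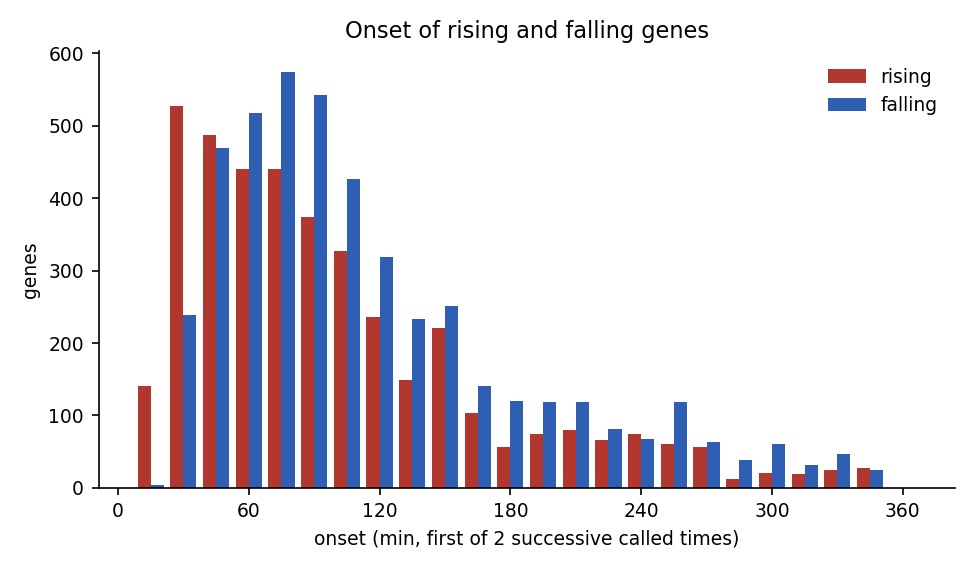
Number of genes by onset time (min), the first of 2 successive times called against 0 min, for rising (red) and falling (blue) genes. 141 rising and 4 falling genes have their onset at 15 min, and 4020 rising and 4606 falling genes have one in all.

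Each time was also compared with the one before, in the fit that leaves out the replicate number. From 0 to 15 min 148 genes were higher and 6 lower, from 15 to 30 min 132 and 36, from 30 to 45 min 47 and 8, from 45 to 60 min 38 and 2, and from 60 to 75 min 6 and 3 (edgeR quasi-likelihood). From 75 to 90 min no gene was called (681 at an unadjusted p under 0.05), 8 and 3 were higher in the next 2 steps, and none was called in any later step, where between 121 and 349 genes had an unadjusted p under 0.05. From 75 min on, the counts at an unadjusted p under 0.05 were below what chance alone gives over 14793 genes. The main fit was therefore conservative for these steps, and an empty step does not show an absence of change. In all 375 genes changed in at least 1 step, or 692 with the replicate number as a block.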

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

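The tests of replicate timing, whole-cell loss and scaling were chosen after the results were seen, and that of the anti-IgM response before.

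The following genes passed the test at both 60 and 360 min against 0 min in opposite directions, and the difference between those times was itself tested (edgeR quasi-likelihood). Usp2 changed by 4.72 and then -1.85, a difference of -6.58 (adjusted p = 4.77e-09), and Tgfb3 by 3.65 and then -2.12, a difference of -5.77 (adjusted p = 1.82e-08). Egr3 changed by 2.05 and then -1.61 (-3.66, adjusted p = 3.44e-10), Spred2 by 1.38 and then -1.68 (-3.06, adjusted p = 3.67e-10), Dusp2 by 1.59 and then -1.11 (-2.70, adjusted p = 8.58e-08) and Inpp5d was higher and then lower, at -2.30 (difference -3.80, adjusted p = 5.28e-13). The interferon-related genes went the other way. Stat2 changed by -1.85 and then 1.13 (2.98, adjusted p = 2.7e-10). Usp18 changed by -1.37 and then 3.75 (5.12, adjusted p = 2.08e-08).

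Several of these calls are lost with 1 library left out or with another method. The fall of Usp2 at 360 min is -1.24 without unstimulated 0 min replicate 2 (adjusted p = 0.257) and -1.69 or -2.05 without anti-IgM 360 min replicate 1 (0.135) or 2 (0.0784), and with limma on log2(TPM + 1) it is -0.37 (adjusted p = 0.271). Without anti-IgM 360 min replicate 1 the falls of Tgfb3 (-1.48, adjusted p = 0.0952) and Dusp2 (-0.79, adjusted p = 0.0765) are not called either. The rise of Stat2 at 360 min is 0.80 with library size alone and 0.93 without unstimulated 0 min replicate 2 or anti-IgM 360 min replicate 2, under the fold minimum, and with limma on log2(TPM + 1) it is 0.88 (adjusted p = 0.131). The rise of Spred2 at 60 min is 0.80 with limma on log2(TPM + 1). The fall of Usp18 at 60 min is not called without unstimulated 0 min replicate 1 (-1.61, adjusted p = 0.0563) or 2 (-1.05, 0.226), without anti-IgM 60 min replicate 1 (-1.05, 0.271) or 2 (-1.80, 0.0587), or with only the 4 libraries compared (-1.37, 0.0601).

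Transcripts of other blood cell types fell between 0 and 360 min, with 30 of the 36 tested macrophage, red cell, platelet and NK markers lower. A scaling factor common to all genes of a library is argued against. Relative to the median of all tested genes, which cancels any such factor, the 36 have a median log2 change of -2.56 (quartiles -3.89 and -1.52). The marker lists were taken for this test after their falls were seen. The value cannot tell whether the share of RNA from each cell type changed. Loss of whole macrophages with no other change would lower their transcripts alike only if all came from a uniform population. C1qa, C1qb, C1qc and Csf1r, tested first, left this open (largest difference 1.4 log2 units, SE 0.86 from edgeR, studentized range adjusted p = 0.379). Adgre1, a member of the fixed list, was added after that result (C1qc against Adgre1, difference 4.58, edgeR SE 0.78, studentized range adjusted p = 3.34e-05). This difference argues only against even loss of a uniform population. Unequal loss of different kinds of cells that hold these transcripts would also give it, so loss of whole cells stays open. Loss of whole red cells cannot be told apart from changes within them, since the falls of Alas2 and Hbb-bs, the extremes of 5 genes, differ by 1.46 (edgeR SE 0.55, studentized range adjusted p = 0.0932; in both cell loss tests this p replaced a limit of 2 SE after the values were seen), with genes of 10 or fewer counts at 360 min left out. Macrophages that remained after the depletion of CD43-positive cells and were lost in culture, together with unequal RNA decay or altered expression, could contribute. With 0 unstimulated libraries after 0 min, a response to anti-IgM cannot be told apart from an effect of time in culture.

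Replicate 1 libraries lay further along the response than replicate 2 libraries between 30 and 150 min, a window picked after the values were seen. Over 3689 changing genes the difference between the replicates followed the rate of change at 9 of 9 times, with a median lead of 8.9 min (3.4 to 17.2 min). A constant difference between the series, such as that between animals or preparations, would leave no lead once each gene's mean difference is taken out. With it taken out the lead pooled over all 23 times was 6.5 min (exact sign-flip p = 0.00244). It was above 0 at 17 of the 23 times (exact binomial p = 0.0347), but only at 7 of the 13 times after 150 min. Both tests treat the times as independent, although they come from the same pair of series and neighbouring leads share libraries. The 23 times also include the 9 of the picked window. Neither p therefore decides between a constant difference and a shift in effective time, and a steady shift over the whole course is not shown. No biological explanation was tested.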

How the results depend on the processing

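Only the replicate block with an estimated correlation and the runs without the library richest in mitochondrial counts were chosen after the results were seen. No named call was reversed in the alternatives run for it, and no list call in the 5 run for lists (estimated correlation, replicate block, both, library size alone and fry). At 60 min the larger group turned from higher to lower genes with library size alone, a replicate block (1726 higher and 1853 lower) and limma on either TPM scale (1560 and 1947 lower). With no fold minimum more genes were higher than lower at 180, at 360 and at 360 against 60 min. The counts of called genes stayed within 1.5 times their reported value with DESeq2 size factors, the DESeq2 tests, the spline of time, adjustment pooled over the 24 times, other onset rules and without the library richest in mitochondrial counts. For the values that follow the cause was not tested, except where fewer genes, fewer libraries or another fold minimum make the change by construction.

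With library size as the only scaling, 1029 genes were higher and 2439 lower at 60 min, and 1960 higher at 180 min. With no low-count filter 841 genes changed in a 15 min step. With a mean of at least 5 CPM, which tests fewer genes, 5218 genes changed over the course and 2447 rose with an onset; 474 were higher at 30 min, 1038 higher and 903 lower at 60 min, 1881 and 1994 at 180 min, 1920 and 2043 at 360 min, and 1372 and 1687 at 360 against 60 min. With the replicate number as a block 692 genes changed in a step and 448 were lower at 30 min.

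With only the 4 libraries compared, 467 genes were higher and 156 lower at 30 min and 828 lower at 60 min. Limma on log2(TPM + 1) found 371 genes higher at 30 min, 799 at 60 min, 1632 at 180 min and 2069 at 360 min, and 1793 lower at 360 against 60 min; on log2(TPM + 0.1) it found 459, 964 and 1894 higher at 30, 60 and 180 min. With no fold minimum 1658 genes were higher and 754 lower at 30 min, 2977 and 2320 at 60 min, and 3722 higher at 360 against 60 min. With a log2 change of at least 2 the counts were 217 and 34 at 30 min, 528 and 379 at 60 min, 1364 and 1848 at 180 min, 1346 and 2269 at 360 min, and 648 and 1542 at 360 against 60 min. Leaving out each library in turn gave 899 to 1645 genes lower at 60 min; a time left with 1 library is assumed to vary like the others.

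Of the 59 list calls against 0 min, 0 were made with an estimated correlation and 0 with a replicate block and an estimated correlation (smallest adjusted p 0.0601); of the 22 at 360 against 60 min these gave 1 and 3. A replicate block alone gave 66 calls and kept 58, library size alone gave 59 and kept 56, and fry gave 81. Of the calls of named genes 5 were lost with library size alone, 0 with a replicate block, 11 without unstimulated 0 min replicate 1, 9 and 8 with limma on log2(TPM + 1) and log2(TPM + 0.1), and 4 with only the 4 libraries compared. At this depth, with 2 libraries per time, 61% of simulated changes of 1.5 log2 units were recovered, in data where most genes were left unchanged.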

Other observations

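The tests of gene length were planned, apart from an exception named below, and the genes described here were chosen after their values were seen.

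Several genes moved differently from other members of the group in which they are usually placed, and some of these groups were themselves mixed. Of 14 T cell markers 3 were higher and 3 lower at 180 min (2 and 4 with library size alone). Of 15 MAPK feedback regulators, a list that holds Rgs16, Rgs2 and Spry1, 7 were higher and 4 lower at 180 min (5 and 6 with library size alone). Cd5, known as a T cell marker and as a negative regulator of B cell receptor signalling, rose from 2.66 ± 0.00394 to 10.2 ± 0.234 CPM (mean ± SD, n = 2) at 180 min (log2 change 1.93, edgeR adjusted p = 5.03e-08). Among regulators of G protein signalling, Rgs16 rose by 5.05 at 180 min while Rgs2 fell by 2.54 by 360 min, and Spry1, an inhibitor of growth factor signalling, rose by 3.10 at 180 min. Among glucose genes Hk2 rose by 3.46 at 360 min and the transporter Slc2a3 fell by 1.94, whereas Slc2a1 stood at 66 ± 12.6 CPM at 0 min and 70 ± 8.1 CPM at 360 min (adjusted p = 0.837).

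Within the B cell regulators, Bach2, a repressor of plasma cell differentiation, fell by 1.28 at 360 min. Bhlhe40 rose by 1.24, or by 0.94, under the fold minimum, with library size alone and also without unstimulated 0 min replicate 1. The lineage factor Ebf1 stood at 233 ± 9.84 and 228 ± 37.3 CPM (adjusted p = 0.887). The lymphotoxin gene Ltb fell by 4.28 to 13.1 ± 0.64 CPM. The activation marker Cd69 was abundant before stimulation, at 767 ± 148 CPM, and stood at 943 ± 129 CPM at 60 min (adjusted p = 0.661). Mcl1, a survival gene, stood at 635 ± 18.5 CPM at 0 min and 394 ± 6.73 CPM at 360 min, a change of -0.69 that is under the fold minimum.

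Sex-linked transcripts were present in both replicate series, and their difference was not tested. The median over the 25 times was 22.4 CPM in replicate 1 and 7.96 CPM in replicate 2 for Xist, 22.8 and 16.1 CPM for Kdm5d, 16.6 and 12.4 CPM for Uty, 146 and 156 CPM for Ddx3y, and 40.9 and 45.4 CPM for Eif2s3y. The pools hold male and female mice per the labels.

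A later onset in long genes was the hypothesis behind the length tests, since a transcript of a long gene takes longer to complete. Across 4019 rising genes, which are not independent replicates, onset and genomic length had a Spearman rho of -0.08, so there was no such trend to explain. With exonic length, mean CPM and peak change taken out it was -0.02 (permutation p = 0.3, 100000 permutations), so no later onset with length was seen across all rising genes. Onset was read in steps of 15 min, so delays shorter than that would largely escape this test, and transcription time is not excluded. With only mean CPM and peak change taken out the rho was -0.08, which decides nothing about weak genes, since it moved nothing. The median onset was 90 min for genes under 10 kb and 75 min in each longer class, while the share with an onset by 45 min was 24.5% under 10 kb, 30.1% from 10 to 30 kb, 33.9% from 30 to 100 kb and 22.6% over 100 kb. These shares leave a delay confined to the longest genes open, which was not tested. Among falling genes the shares were 14%, 20.3%, 17.3% and 5.5%. Across 4605 falling genes the partial rho was 0.09 (permutation p = 1e-05, the smallest these permutations can give).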
